A study of Mus musculus with 8 samples.

How the data were processed

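The study measured bulk RNA sequencing of total RNA from the femurs of neonatal mice aged 3 to 5 days. Skeletal stem cells (SSC) and bone cartilage stromal progenitors (BCSP) were isolated by fluorescence-activated cell sorting from wild-type and Tet1 knockout (KO) mice. Each of the 4 groups held 2 libraries, whose titles number them round 1 and round 2, and the text calls them library 1 and library 2 of their group. The labels do not say whether the 2 libraries of a group come from separate animals or pools, so each p-value measures only the spread between these samples. Every sample carries the same strain name, B6;129S4-Tet1tm1.1Jae/J, wild type included. The sex of the pups is not given in the sources used here. Reads were paired and 150 bases long, per the labels.

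The deposited table holds counts per gene for the 8 libraries, in a unit of counts that its whole-number values fit. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with the mouse build mm10, with no versions given. The table's own name points to htseq, so which program counted the reads is not settled by the sources used here. The annotation release and the strand of counting are not stated. Antisense transcripts can therefore not be told apart from sense ones, and reads shared by close paralogs may sit with either. In the column names, SCC was read as SSC and BCP as BCSP, because the titles hold exactly 1 such sample each. Of the 55471 gene entries, 55230 matched GENCODE release M21, from which positions and exon lengths were taken. Of all entries, 22325 had 0 counts in every library and 235 shared a symbol with another entry.

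Library totals ran from 104782544 to 168004119 counts, and 22039 to 25782 genes had at least 1 count in a library. At these depths 1 CPM (count per 1e6 counts) stands for more than 100 counts. The tested genes held 99.9854% of all counts. Within each group, the 2 libraries differed far more than repeated sequencing of 1 library would, with chi-square per degree of freedom of 142 to 348, so neither is a resequenced copy of the other. Correlations of log2 CPM were 0.939 to 0.959 within groups and 0.924 to 0.969 between groups.

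Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with the packages limma (3.58.1) and data.table (1.17.8). Counts were scaled by TMM factors (0.854 to 1.06) and filtered by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 22153 genes. A quasi-likelihood model with robust dispersion was fitted to all 8 libraries, with 1 mean per group. Its contrasts were KO against wild type in SSC, KO against wild type in BCSP, their difference (SSC minus BCSP, the interaction), and SSC against BCSP in each genotype. The genotype effect over both cell types came from an additive model of cell type and genotype. Residual degrees of freedom were 4, and 5 in the additive model. The additive model treats SSC and BCSP libraries as independent samples. The labels do not say whether they share animals within a round, in which case its p-values could be too small. Common biological variation was 0.525, and the median of the trended value in genes of at least 1 CPM was 0.231. Benjamini-Hochberg adjustment was applied over all tested genes, with 0.05 as the threshold. Log2 fold changes are given with their standard errors (SE), and CPM as mean ± SD. Log CPM used a prior count of 2.

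Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 35 lists. The lists were cartilage matrix and chondrocyte, hypertrophic chondrocyte, osteoblast and mineralisation, adipogenic and marrow stromal, and skeletal stem cell and sort markers. With them came tendon, ligament and fibrous matrix, and matrix proteases with osteoarthritis-linked genes. The tendon list, as it is called for short, holds many collagen and other matrix genes that are not particular to tendon. Signalling and state lists were inflammatory cytokines and NF-kB, interferon response, senescence and p53, TGF-beta, BMP, Wnt, Hedgehog, Notch, and immediate-early and heat-shock genes. Further lists were S phase, G2 and M phase, glycolysis and hypoxia, oxidative phosphorylation, endoplasmic reticulum (ER) stress, DNA methylation machinery, imprinted genes, and germline genes under promoter methylation. Other cell types were covered by erythroid, neutrophil, macrophage and osteoclast, lymphoid, mast cell and megakaryocyte, endothelial, pericyte and smooth muscle, skeletal muscle, Schwann cell, and keratinocyte lists. A list of 5 sex-linked genes checked the libraries. Lists needed at least 5 tested members. Ahsp was the one listed gene missing from the table, and the 26 symbols of the glycolysis list matched 27 table entries. Where members of a list had 0 counts in a whole group, the median was also taken with those members set at 3 counts over the group.

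The comparisons, lists, threshold, alternatives and rule for naming genes were set before the data were examined. That rule named Tet1, then up to 10 genes per direction that passed with at least 5 CPM in the higher group and KO libraries beyond both wild-type ones. Secondary comparisons allowed 8, and the interaction 5. Where fewer than 5 passed, the genes of lowest p filled the direction up to 5, given as not passing, and predicted gene models were not named. For lists, the rule gave up to 4 passing members, or else the 2 of lowest p. This part was followed only for lists that passed camera in the same comparison, a restriction made after the values were seen. Cd59a and Ulbp1 lie under 5 CPM and outside the rule. They are named because so few genes passed, and this was chosen after the values were seen. Of the genes the rule gave for lists, 2 are not reported here.

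The pipeline was tested on simulated data of the same size and spread, with 200 changed genes. Of changes of 2, 4 and 8-fold, it recovered 26.9, 83.6 and 98.5% in SSC, 29.9, 85.1 and 97% in BCSP, and 62.7, 91 and 98.5% over both cell types. False calls were 15 of 154, 8 of 149 and 11 of 181. Of the 35 lists, none of which was shifted, camera called 0, 0 and 1. Genes were simulated independently of one another, so this does not measure false calls among lists whose genes move together. With 200 changed genes, the adjusted threshold was met at larger p-values than in the real data, where few genes passed. The recovered shares may therefore be too high for the real data.

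Alternatives were RLE scaling, no filter beyond all-zero genes, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, the round as a block, each library left out in turn, and a minimum log2 fold change of 1. Others were fitting only the 4 libraries compared, the mean of the 2 genotype contrasts, an estimated correlation or fry for lists, and other gene sets or windows for the agreement and position checks. After the data were seen, limma-voom with quality weights, the mean level of Ddx3y, Eif2s3y, Kdm5d and Uty as a covariate, and a fit without both BCSP libraries of round 2 were added. Genes within 20 Mb of Tet1 were compared with all others by Fisher's exact test. That test takes genes as independent units, which they are not, so its p-values may be too small. The agreement of the genotype effects in SSC and BCSP was measured by Pearson correlation across genes, which are not independent of one another. A trend with exon length was measured by Spearman correlation in the 9523 genes with a mean of at least 5 CPM. All 8 libraries were used, and no column held values of a sample outside the series. Splicing and exon use were left out, since the table holds a single count per gene.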

Results

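Tet1, the dioxygenase gene (mm10 chr10:62804570-62908996) targeted in the KO mice, was counted at 15.6 and 19.6 CPM in the wild-type SSC libraries 1 and 2 and at 7.26 and 11.8 CPM in KO SSC. In BCSP it was counted at 21.6 and 10.98 CPM in wild type and at 10.8 and 11.97 CPM in KO, so wild-type BCSP library 2 lay within the KO range. The log2 fold change of Tet1 was -0.89 ± 0.34 (SE) in SSC, -0.52 ± 0.34 in BCSP and -0.70 ± 0.23 over both, with edgeR adjusted p of 1, 0.687 and 0.608. The BCSP value of Tet1 was 0.05 without wild-type BCSP library 1. The targeted allele removes an internal exon as far as is known, so counts over the whole gene are a weak check of genotype. The other dioxygenase genes did not pass: Tet2 was 0.57 ± 0.27 and Tet3 0.35 ± 0.17 over both cell types, with edgeR adjusted p of 0.628 and 0.633. The DNA methyltransferase genes were 0.03 ± 0.14 for Dnmt1, 0.05 ± 0.16 for Dnmt3a and -0.13 ± 0.26 for Dnmt3b.

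**Figure D1:**
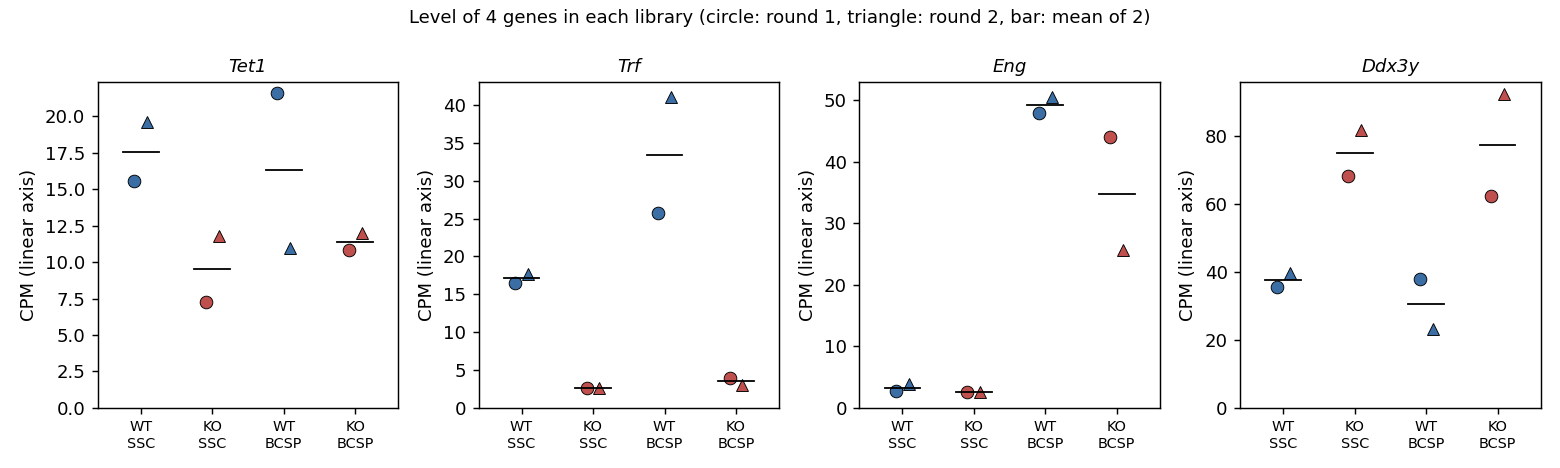
CPM (linear axes from 0) of Tet1, Trf, Eng and Ddx3y in each of the 8 libraries of the 4 groups, with circles for library 1, triangles for library 2 and bars for the mean of 2. Trf averaged 17.1 CPM in wild-type SSC and 2.63 CPM in KO SSC.

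Cartilage transcripts filled much of each library. Col2a1, the main fibrillar collagen of cartilage, took 24.7 to 30.6% of all counts, and with the collagen gene Col11a2 and the matrix protein gene Sparc it took 28.5 to 34.7%. These 3 genes showed no genotype difference that passed, at -0.07 ± 0.34, -0.17 ± 0.31 and 0.06 ± 0.32 in SSC. Transcripts of red blood cells varied, with globin genes at 34.1 CPM in wild-type SSC library 1 and 1.92 to 14.5 CPM in the others. Deviation of a library from the mean correlated with exon length, at Spearman -0.611 in wild-type BCSP library 2 and 0.474 in KO BCSP library 2, and -0.313 to 0.336 in the other 6. Those 2 BCSP libraries lay farthest from the rest on the first 2 principal components, at 128.46 on the second and 121.75 on the first. Hoxd13, a homeobox gene of the foot and hand plate, averaged 24.8 CPM in the 4 libraries of round 1 and 0.181 CPM in the 4 of round 2, a difference balanced over the genotypes.

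**Figure D2:**
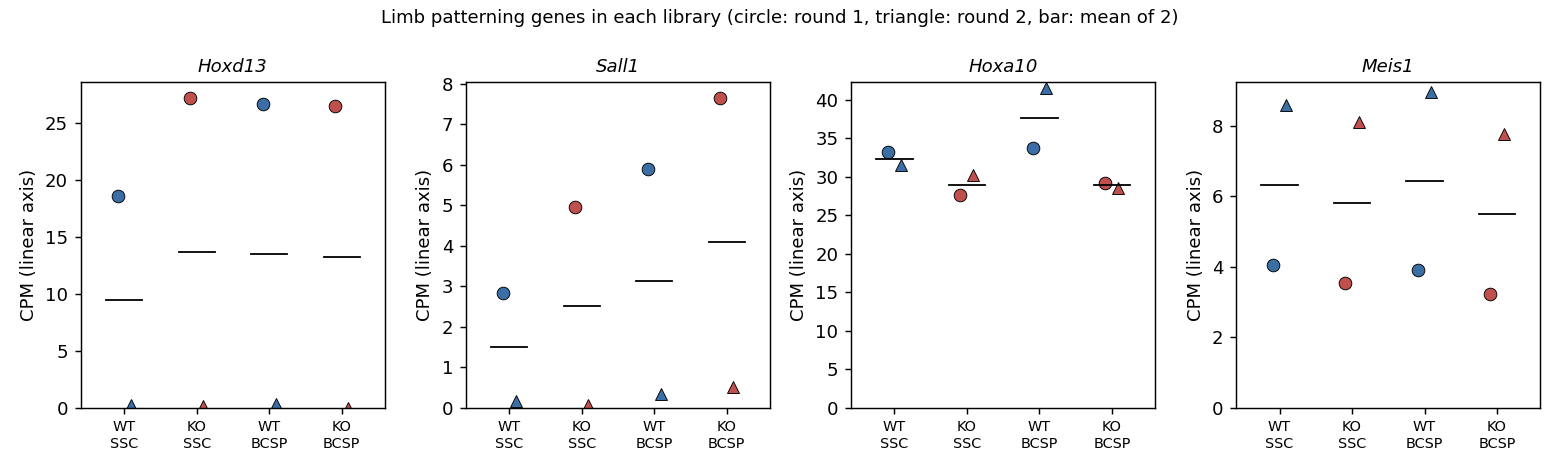
CPM (linear axes from 0) of the limb patterning genes Hoxd13, Sall1, Hoxa10 and Meis1 in each of the 8 libraries of the 4 groups, with circles for library 1, triangles for library 2 and bars for the mean of 2. Sall1 averaged 5.34 CPM in the libraries of round 1 and 0.274 CPM in those of round 2.

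In SSC, Trf was the one gene that passed for genotype. Trf (chr9:103204001-103230444) encodes transferrin, the iron carrier of plasma that chondrocytes also express. It fell from 17.1 ± 0.845 CPM (SD, n = 2) in wild type to 2.63 ± 0.0559 CPM in KO, a log2 fold change of -2.70 ± 0.29 (edgeR adjusted p = 0.0109). Among genes that did not pass (edgeR adjusted p = 1), the lowest p-values on the higher side belonged to Tbx4, Zfp365 and Y-linked genes. Tbx4, a hindlimb transcription factor gene, stood at 15.5 ± 4.3 CPM in wild type and 27.5 ± 0.0106 in KO (0.82 ± 0.24). Zfp365, a zinc-finger gene linked to DNA repair, stood at 10.2 ± 3.79 and 20.3 ± 7.37 CPM (0.99 ± 0.32). The Y-linked genes Ddx3y, Eif2s3y and Uty had log2 fold changes of 0.99 ± 0.28, 0.98 ± 0.31 and 0.91 ± 0.29. On the lower side, the peptide hormone gene Adm2 was at -1.21 ± 0.29 and Rlbp1, a retinoid-binding protein gene, at -0.91 ± 0.28. The lysosomal channel gene Mcoln3 was at -1.50 ± 0.44, and Acta1, the actin gene of skeletal muscle, at -1.82 ± 0.56.

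The edgeR test called 1 of 22153 genes in SSC, with 266 at an unadjusted p under 0.05 against 1107.6 expected from chance alone. DESeq2 called 9, limma-voom 1 and edgeR without a filter 4. Leaving out any 1 of the 4 SSC libraries ended the call on Trf: its edgeR adjusted p was 0.068 without wild-type library 1 and 0.116 without wild-type library 2. It was 0.294 without KO library 1 and 0.224 without KO library 2, with log2 fold changes of -2.75 to -2.66. With the level of Y-linked genes, which itself differs with genotype, as a covariate, Trf was at -2.01 (edgeR adjusted p = 0.601).

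As groups, genes of cell division and of energy metabolism lay lower in KO SSC, while tendon or fibrous matrix genes and TGF-beta genes lay higher. No member of the lists named here passed on its own over all genes by edgeR. S-phase genes, which serve DNA replication, had a median log2 fold change of -0.24 with 23 of 25 below 0 (camera adjusted p = 0.000115, adjusted p = 0.645 with an estimated correlation). Examples are Ccne1 (-0.63 ± 0.43) and Cdc6 (-0.48 ± 0.35). G2 and M phase genes, which serve mitosis, had a median of -0.18 with 20 of 25 below 0 (camera adjusted p = 0.0113, adjusted p = 0.724 with an estimated correlation), among them Ttk (-0.45 ± 0.42). These genes also followed the round. Their median deviation from each gene's mean log2 CPM was 0.54 in wild-type and 0.52 in KO SSC library 1. In library 2 it was -0.20 and -0.77, so the genotypes parted mainly there. Glycolysis and hypoxia genes had a median of -0.28 with 18 of 27 below 0 (camera adjusted p = 0.000115, adjusted p = 0.645 with an estimated correlation). The lactate exporter gene Slc16a3 went from 123 to 69.3 CPM and the glycolytic enzyme gene Pgam1 from 118 to 76.0 CPM. Oxidative phosphorylation genes had a median of -0.13 with 26 of 28 below 0 (camera adjusted p = 0.0283, adjusted p = 0.751 with an estimated correlation), among them Cycs (-0.27 ± 0.24). ER stress genes, with Manf (-0.54 ± 0.29) and Creld2 (-0.51 ± 0.27), had a median of -0.13 with 14 of 22 below 0 (camera adjusted p = 0.0283, adjusted p = 0.645 with an estimated correlation).

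Cartilage matrix genes also lay lower in KO SSC, with a median of -0.13 and 19 of 25 below 0 (camera adjusted p = 0.0283, adjusted p = 0.67 with an estimated correlation). Epyc, a proteoglycan gene of epiphyseal cartilage, stood at 462 ± 36.3 and 304 ± 73.8 CPM, while the lubricin gene Prg4 averaged 364 and 537 CPM. Tendon, ligament and fibrous matrix genes had a median of 0.14 with 17 of 22 above 0 (camera adjusted p = 0.00422, adjusted p = 0.553 with an estimated correlation). The tenomodulin gene Tnmd was at 0.81 ± 0.27. Stem cell and sort marker genes, with the receptor gene Pdgfra (0.45 ± 0.23), had a median of 0.14 with 16 of 18 above 0 (camera adjusted p = 0.0337, adjusted p = 0.594 with an estimated correlation). TGF-beta genes, with the receptor gene Acvrl1 (0.70 ± 0.28) and the repressor gene Tgif1 (0.53 ± 0.22), had a median of 0.11 with 21 of 25 above 0 (camera adjusted p = 0.0155, adjusted p = 0.553 with an estimated correlation). Inflammatory genes had a median of 0.36 but a mean of -0.06, with 15 of 25 above 0 (camera adjusted p = 0.0437 for higher, adjusted p = 0.724 with an estimated correlation). In that list the chemokine gene Cxcl1 stood at 97.9 and 36.8 CPM, and the cytokine gene Lif at 49.2 and 91.9 CPM. No member of these 5 lists passed on its own over all genes by edgeR.

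Markers of sex moved with genotype in SSC, while those of blood cells were high in wild-type SSC library 1. No member of these lists passed over all genes by the main edgeR test. Globin genes stood at 34.1 CPM in that library, 2.18 in wild-type library 2 and 4.03 and 1.92 in KO, so wild-type library 2 lay within the KO range. Erythroid genes had a median of -1.78 with 11 of 12 below 0 (camera adjusted p = 7.52e-05, adjusted p = 0.553 with an estimated correlation). Lymphoid genes had a median of -1.16 with 6 of 9 below 0 (camera adjusted p = 0.0377, adjusted p = 0.594 with an estimated correlation). The antibody gene Igkc in it averaged 21.4 CPM in wild-type SSC and 0 in KO. Igkc was called in SSC by DESeq2 (adjusted p = 0.000104) and by edgeR with the round as a block. Neutrophil genes, at a median of -3.29 with 17 of 17 below 0, were not called (camera adjusted p = 0.0872, adjusted p = 0.751 with an estimated correlation). The 5 sex-linked genes had a median of 0.91, with 4 above 0 and Xist below (camera adjusted p = 7.52e-05, adjusted p = 0.553 with an estimated correlation). Adjusted over that list alone by edgeR, the 4 Y-linked genes rose and Xist fell. Log2 fold changes in SSC correlated with exon length at Spearman 0.283 across 9523 genes. Among random lists matched on length and expression, the called cartilage, oxidative phosphorylation and ER stress lists lay within the central 95% (percentiles 2.63, 27.1 and 10.3), so a shift with length stays open for them.

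Each call on a list in SSC depended on single libraries, and camera with an estimated correlation called 0 of the 13 lists and fry 0. With the Y-linked level as a covariate, 8 of the 13 changed side and 0 kept their call. Without wild-type SSC library 1, camera kept 3 of the 13. The lost calls had adjusted p of 0.163 (cartilage), 0.541 (sort markers), 0.973 (inflammatory and lymphoid), 0.251 (TGF-beta), 0.493 (S phase and ER stress) and 0.586 (erythroid, median -0.03). G2 and M phase genes then had a median of 0.24 and oxidative phosphorylation genes 0.10. Without KO SSC library 2, camera also called 3 of the 13, but 1 of them turned: G2 and M phase genes were higher at 0.29 (camera adjusted p = 5.36e-06). The lost calls then had adjusted p of 0.294 (cartilage), 0.509 (sort markers), 0.228 (tendon), 0.521 (inflammatory, median -0.23), 0.28 (TGF-beta and lymphoid), 0.99 (S phase), 0.784 (oxidative phosphorylation), 0.323 (ER stress) and 0.204 (sex-linked). Without KO SSC library 1 the glycolysis and lymphoid calls were lost (0.111 and 0.0531), while S phase moved to -0.54 and G2 and M phase to -0.91. Without wild-type SSC library 2 the cartilage call was lost (0.0866), and oxidative phosphorylation moved to -0.37. The inflammatory call was also lost without wild-type BCSP library 1 or 2 (0.0882 and 0.103). Medians also moved, without wild-type library 1 to -0.08 (cartilage), 0.04 (tendon), 0.10 (inflammatory), -0.06 (S phase), -0.04 (ER stress) and -0.48 (lymphoid), and without KO library 2 to -0.04 (tendon), 0.02 (TGF-beta), -0.04 (S phase), -0.01 (oxidative phosphorylation), -0.03 (ER stress) and -3.16 (lymphoid). Without KO library 1 they were 0.26 (sort markers and tendon), 0.72 (inflammatory), 0.24 (TGF-beta) and -0.36 (oxidative phosphorylation), and without wild-type library 2 they were 0.23 (sort markers), 0.78 (inflammatory), 0.26 (TGF-beta), -0.46 (S phase), -0.50 (G2 and M phase), -0.14 (glycolysis) and -0.21 (ER stress).

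In BCSP, Trf was again the one gene that passed for genotype. It fell from 33.4 ± 10.9 CPM (SD, n = 2) in wild type to 3.50 ± 0.663 CPM in KO, a log2 fold change of -3.26 ± 0.30 (edgeR adjusted p = 0.0016). Genes with the next lowest p-values did not pass (edgeR adjusted p = 0.686). Nes, which encodes the progenitor filament protein nestin, stood at 10.3 ± 2.73 CPM in wild type and 29.8 ± 5.86 in KO (1.53 ± 0.30). Zfp365 stood at 9.27 ± 0.707 and 26.6 ± 4.86 CPM (1.52 ± 0.32), and the tenascin gene Tnxb at 4.81 ± 0.339 and 12.5 ± 2.86 (1.37 ± 0.31). Hivep3, a zinc-finger regulator of bone matrix, was at 1.55 ± 0.37 and the Y-linked Ddx3y at 1.34 ± 0.28. On the lower side, Pstpip2, an adaptor gene of myeloid cells and osteoclasts, was at -1.70 ± 0.37 and the myosin gene Myo15 at -1.41 ± 0.32. Rlbp1 was at -1.37 ± 0.28 and the antigen-loading gene H2-DMb1, 1 of several close paralogs, at -1.43 ± 0.32.

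The edgeR test called 1 of 22153 genes in BCSP, with 1371 at an unadjusted p under 0.05. DESeq2 called 20 (7 higher, 13 lower), among them Nes, Pstpip2, Hivep3, Tnxb, Zfp365, Rlbp1, Myo15 and Ddx3y, while limma-voom called 1 and edgeR without a filter 38. Trf passed without any single library, with log2 fold changes of -3.55 to -2.88. It did not pass without both BCSP libraries of round 2 (-2.69, edgeR adjusted p = 0.182) or with the Y-linked level as a covariate (-2.48, edgeR adjusted p = 1).

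Genes of energy metabolism and cell division lay lower in KO BCSP as groups, and inflammatory, protease and TGF-beta genes lay higher. No member of these lists passed on its own over all genes by edgeR. All 28 oxidative phosphorylation genes were below 0, with a median of -0.51 (camera adjusted p = 7.3e-09, adjusted p = 0.702 with an estimated correlation). Ndufs7 and Ndufa4, which encode parts of respiratory complexes, went from 22.9 to 12.98 and from 27.6 to 14.7 CPM. S-phase genes had a median of -0.45 with 23 of 25 below 0 (camera adjusted p = 0.000104, adjusted p = 0.702 with an estimated correlation), among them the helicase genes Mcm3 (-0.57 ± 0.25) and Mcm2 (-0.56 ± 0.26). G2 and M phase genes, with the kinase gene Aurka (-0.86 ± 0.39), had a median of -0.53 with 23 of 25 below 0 (camera adjusted p = 0.00104, adjusted p = 0.702 with an estimated correlation). Glycolysis and hypoxia genes had a median of -0.43 with 18 of 27 below 0 (camera adjusted p = 0.00423, adjusted p = 0.702 with an estimated correlation), among them Slc16a3 (-0.80 ± 0.30) and Pgam1 (-0.68 ± 0.27). Cartilage matrix genes had a median of -0.13 with 17 of 25 below 0 (camera adjusted p = 0.045, adjusted p = 0.702 with an estimated correlation), and Epyc averaged 355 and 208 CPM. ER stress genes, with Pdia4 (-0.52 ± 0.24) and Sdf2l1 (-1.16 ± 0.38), had a median of -0.14 with 16 of 22 below 0 (camera adjusted p = 0.0463, adjusted p = 0.702 with an estimated correlation).

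Inflammatory genes had a median of 0.72 in BCSP with 21 of 25 above 0 (camera adjusted p = 0.00104, adjusted p = 0.702 with an estimated correlation). Lif stood at 56.3 ± 14 CPM in wild type and 147 ± 31.7 in KO, and the NF-kB subunit gene Relb at 32.4 ± 11.7 and 62.2 ± 21.2. Protease and osteoarthritis-linked genes had a median of 0.32 with 18 of 24 above 0 (camera adjusted p = 0.00921, adjusted p = 0.463 with an estimated correlation). Epas1, a hypoxia factor gene tied to cartilage breakdown, stood at 16.9 ± 5.94 and 32.3 ± 1.09 CPM, and the nitric oxide synthase gene Nos2 at 1.97 ± 1.31 and 5.42 ± 0.531. TGF-beta genes had a median of 0.25 with 20 of 25 above 0 (camera adjusted p = 0.00921, adjusted p = 0.423 with an estimated correlation). The latent TGF-beta binding gene Ltbp2 was at 1.01 ± 0.32, and Tgfbi, a matrix gene induced by TGF-beta, at -0.82 ± 0.31.

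Markers of some other cell types were higher in KO BCSP at low counts. Lymphoid and skeletal muscle genes lay the other way, with medians of -0.35 and -0.14, and were not called. Pericyte and smooth muscle genes, with Notch3 (3.63 and 6.98 CPM), had a median of 0.74 with 11 of 13 above 0 (camera adjusted p = 0.00157, adjusted p = 0.423 with an estimated correlation). Endothelial genes, with Tie1 (0.0174 and 0.661 CPM) and Esam (0.00874 and 0.38 CPM), had a median of 0.57 with 11 of 16 above 0 (camera adjusted p = 0.00948, adjusted p = 0.463 with an estimated correlation). The 8 mast cell and megakaryocyte genes, 2 of them at 0 in a whole group, were all above 0 with a median of 1.75, also with those 2 set at 3 counts (camera adjusted p = 0.00253, adjusted p = 0.423 with an estimated correlation). Neutrophil genes, at a median of 1.53 with 17 of 17 above 0, were not called (camera adjusted p = 0.0973, adjusted p = 0.795 with an estimated correlation). Sex-linked genes had a median of 0.91, and 3 rose when adjusted over that list alone by edgeR (camera adjusted p = 0.000234, adjusted p = 0.524 with an estimated correlation). Log2 fold changes in BCSP correlated with exon length at Spearman 0.513, with medians of -0.37 in the shortest 25% of 9523 genes and 0.15 in the longest 25%. Random lists matched on length and expression covered the called cartilage, ER stress and endothelial lists in their central 95% (percentiles 62.2, 94.3 and 87). For ER stress their median of -0.28 lay below that of the list. A shift with length stays open at least for these 3.

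Of the 13 lists called in BCSP, camera with an estimated correlation called 0 and fry 2, the mast cell and pericyte lists. With the Y-linked level as a covariate, 7 of the 13 changed side and 0 kept their call. Oxidative phosphorylation genes kept their call without any single library, at -0.18 without wild-type BCSP library 2, -0.27 without KO BCSP library 2, -0.79 without wild-type library 1 and -0.82 without KO library 1. Their median was 0.10 without both libraries of round 2 (camera adjusted p = 0.346). Leaving out wild-type BCSP library 1 lost calls, with camera adjusted p of 0.201 (proteases), 0.777 (inflammatory, median 0.28), 0.16 (TGF-beta and pericyte), 0.522 (G2 and M phase, median -0.22) and 0.105 (ER stress and mast cell). Glycolysis then moved to -0.79 and endothelial genes to 1.02. Without wild-type BCSP library 2 they were 0.595 (cartilage, median 0.01), 0.63 (glycolysis, median 0.05), 0.286 (ER stress) and 0.0645 (endothelial). Without KO BCSP library 1 they were 0.0589 (proteases), 0.0639 (TGF-beta), 0.0715 (glycolysis) and 0.0737 (mast cell). Without KO BCSP library 2 they were 0.342 (cartilage), 0.186 (inflammatory, median 0.26), 0.479 (ER stress) and 0.0745 (G2 and M phase and endothelial), S phase moved to -0.27 and sex-linked genes to 0.58. The cartilage call was also lost without any 1 of the SSC libraries (0.0501 to 0.0728), and the ER stress call without KO SSC library 1 or 2 (0.0571 and 0.0728). Medians also moved, without wild-type library 1 to -0.21 (cartilage), 0.21 (proteases), -0.29 (ER stress) and 4.76 (mast cell), and without KO library 1 to -0.28 (cartilage), -0.21 (ER stress), 0.72 (mast cell) and 0.48 (pericyte). Without KO library 2 they were -0.03 (cartilage), 0.18 (proteases), -0.25 (G2 and M phase), -0.09 (ER stress) and 0.10 (endothelial), and without both libraries of round 2 they were -0.21 (S phase), -0.10 (endothelial) and 0.39 (sex-linked).

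**Figure D3:**
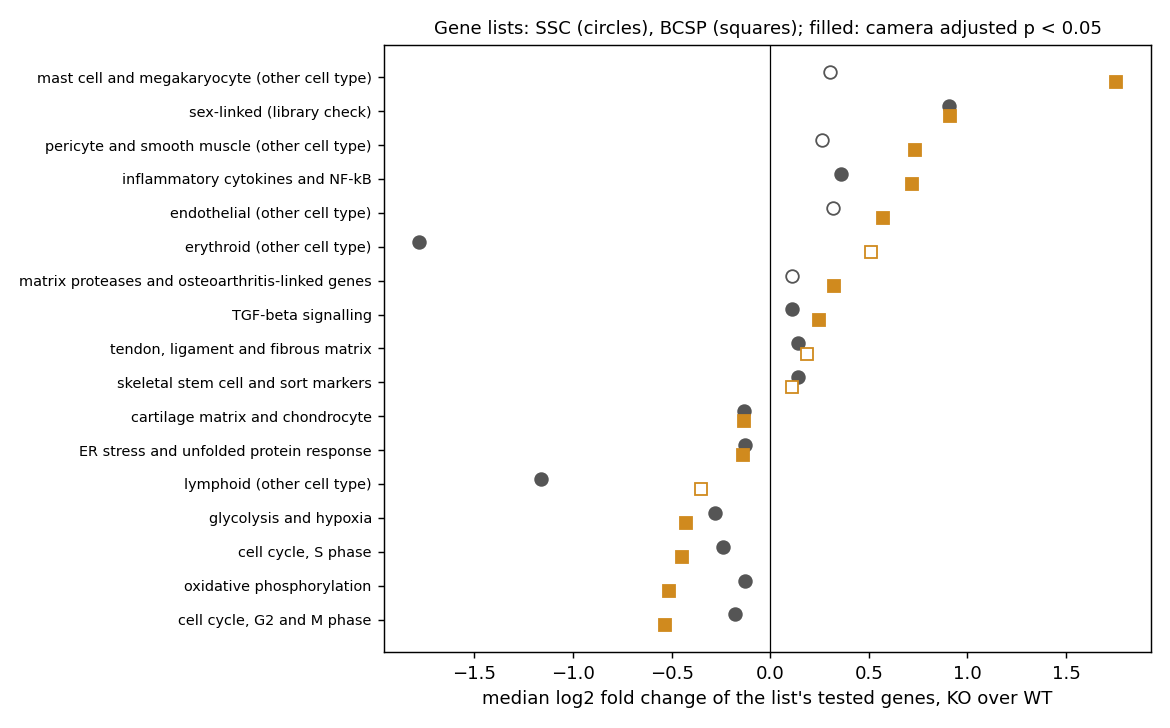
Median log2 fold change, KO over wild type, of the tested genes in 17 lists, with circles for SSC, squares for BCSP and filled symbols where the camera adjusted p was under 0.05. Oxidative phosphorylation genes had medians of -0.13 in SSC and -0.51 in BCSP.

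Over both cell types, 3 genes passed for genotype, and all 3 fell in KO. Trf fell with a log2 fold change of -2.98 ± 0.21 (edgeR adjusted p = 3.81e-05). Cd59a (chr2:104095801-104115354), which encodes an inhibitor of complement lysis, fell with one of -2.55 ± 0.35 (edgeR adjusted p = 0.0427). Its levels were 3.16 ± 0.835 and 0.451 ± 0.0112 CPM in wild-type and KO SSC, and 3.45 ± 2.04 and 0.705 ± 0.0941 CPM in BCSP (SD, n = 2). Ulbp1 (chr10:7440362-7473638), a gene for a ligand of a natural killer cell receptor, fell with one of -2.94 ± 0.41 (edgeR adjusted p = 0.0427), from 1.87 to 0.324 CPM in SSC and from 2.17 to 0.212 CPM in BCSP. Genes next in order did not pass by edgeR: Pstpip2 (-1.57 ± 0.24, adjusted p = 0.0692), Adm2 (-1.21 ± 0.19, 0.0753), Myo15 (-1.28 ± 0.21, 0.0753) and Rlbp1 (-1.14 ± 0.20, 0.104). On the higher side were Ddx3y (1.17 ± 0.19, edgeR adjusted p = 0.0753), Nes (1.20 ± 0.21, 0.127), Zfp365 (1.26 ± 0.23, 0.127) and Tnxb (1.12 ± 0.21, 0.15). The chemokine gene Cxcl12, a product of marrow stroma, was at 0.96 ± 0.18 (edgeR adjusted p = 0.15).

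Of 22153 genes, 1753 had an unadjusted p under 0.05 in this comparison, 875 higher and 878 lower. DESeq2 called 103 (44 higher, 59 lower), among them Ddx3y, Pstpip2, Adm2, Myo15, Rlbp1, Nes, Zfp365, Tnxb and Cxcl12. Limma-voom called 8 and edgeR without a filter 234. With the round as a block edgeR called 28, 10 higher and 18 lower. Trf passed without each library in turn (-3.06 to -2.77) but not with the Y-linked level as a covariate (-2.18, edgeR adjusted p = 0.519). Ulbp1 did not pass without each of the 8 libraries in turn (edgeR adjusted p 0.0785 to 0.259). Cd59a passed without wild-type BCSP library 1 (edgeR adjusted p = 0.0106) and not without each of the other 7 (0.0785 to 0.284).

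The gene groups called in both populations were called in the joint model too. Glycolysis and hypoxia genes had a median of -0.36 with 19 of 27 below 0 (camera adjusted p = 4.22e-05, adjusted p = 0.498 with an estimated correlation). Adjusted over that list alone by edgeR, 8 of its genes fell, with Slc16a3 at -0.82 ± 0.20 and Pgam1 at -0.66 ± 0.18 as those of lowest p. S-phase genes had a median of -0.36 with 23 of 25 below 0 (camera adjusted p = 5.93e-07, adjusted p = 0.498 with an estimated correlation), among them Mcm2 (-0.45 ± 0.17) and Mcm5 (-0.58 ± 0.23). G2 and M phase genes, with Aurka (-0.56 ± 0.27), had a median of -0.31 with 24 of 25 below 0 (camera adjusted p = 0.000222, adjusted p = 0.635 with an estimated correlation). Oxidative phosphorylation genes, with Ndufa4 (-0.60 ± 0.24), had a median of -0.33 with 27 of 28 below 0 (camera adjusted p = 3.2e-07, adjusted p = 0.498 with an estimated correlation). Cartilage matrix genes had a median of -0.13 with 18 of 25 below 0 (camera adjusted p = 0.00663, adjusted p = 0.498 with an estimated correlation), and Epyc (-0.69 ± 0.17) fell when adjusted over the list alone by edgeR. ER stress genes, with Sdf2l1 (-0.81 ± 0.27), had a median of -0.17 with 14 of 22 below 0 (camera adjusted p = 0.00663, adjusted p = 0.498 with an estimated correlation).

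On the higher side, inflammatory genes had a median of 0.47 with 16 of 25 above 0 (camera adjusted p = 0.000618, adjusted p = 0.498 with an estimated correlation). Adjusted over the list alone by edgeR, 1 gene in it rose, and the gene of lowest p was Lif (1.15 ± 0.27), while Cxcl1 was at -1.19 ± 0.37. TGF-beta genes had a median of 0.24 with 20 of 25 above 0 (camera adjusted p = 0.00088, adjusted p = 0.384 with an estimated correlation). In that list 3 genes rose when adjusted over it alone by edgeR, with Acvrl1 (0.71 ± 0.18) and Tgif1 (0.56 ± 0.14) of lowest p. Protease and osteoarthritis-linked genes, with Epas1 (0.70 ± 0.19) and Timp3 (0.72 ± 0.23), had a median of 0.20 with 17 of 24 above 0 (camera adjusted p = 0.00494, adjusted p = 0.384 with an estimated correlation). Tendon, ligament and fibrous matrix genes, with Tnmd (0.56 ± 0.19), had a median of 0.15 with 16 of 22 above 0 (camera adjusted p = 0.0188, adjusted p = 0.498 with an estimated correlation). Pericyte genes, with the growth factor receptor gene Pdgfrb (0.49 ± 0.15), had a median of 0.60 (camera adjusted p = 0.00347, adjusted p = 0.384 with an estimated correlation). Endothelial genes, with the transcription factor gene Erg (0.50 ± 0.14), had a median of 0.49 (camera adjusted p = 0.0465, adjusted p = 0.498 with an estimated correlation). Mast cell genes had a median of 0.74 (camera adjusted p = 0.0127, adjusted p = 0.384 with an estimated correlation) and sex-linked genes 0.91 (camera adjusted p = 5.93e-07, adjusted p = 0.384 with an estimated correlation).

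Of the 14 lists called over both cell types, camera with an estimated correlation called 0 and fry 0, and log2 fold changes correlated with exon length at Spearman 0.468. With the Y-linked level as a covariate, 8 of the 14 changed side and 0 kept their call. Among single libraries, wild-type BCSP library 1 mattered most, since camera kept 7 of the 14 without it. The lost calls had adjusted p of 0.0812 (tendon and pericyte), 0.0711 (proteases), 0.194 (inflammatory), 0.051 (G2 and M phase), 0.101 (mast cell) and 0.0967 (endothelial). Without KO SSC library 2 the camera values were 0.298 (G2 and M phase, median -0.14) and 0.0798 (tendon), and without wild-type SSC library 2 they were 0.0508 (tendon) and 0.102 (endothelial). Without KO BCSP library 1 they were 0.0575 (tendon), 0.0994 (mast cell) and 0.0542 (endothelial). The endothelial call was also lost without wild-type BCSP library 2 (0.107) and KO BCSP library 2 (0.145). Kept medians moved as well, with oxidative phosphorylation at -0.15 and glycolysis at -0.17 without wild-type BCSP library 2. G2 and M phase was at -0.65 without KO SSC library 1, cartilage at -0.04 without wild-type BCSP library 2, and proteases at 0.07 and inflammatory genes at 0.28 without KO BCSP library 2. Without wild-type BCSP library 1, cartilage was at -0.22, proteases at 0.12, inflammatory genes at 0.30 and G2 and M phase at -0.18, and without KO BCSP library 1, proteases were at 0.13 and mast cell genes at 0.43. Cartilage was at -0.07 without KO SSC library 2, and without KO BCSP library 2 cartilage was at -0.07, G2 and M phase at -0.19 and oxidative phosphorylation at -0.20. Tendon genes were at 0.08 and G2 and M phase at -0.20 without wild-type SSC library 1, G2 and M phase was at -0.49 without wild-type SSC library 2, and oxidative phosphorylation was at -0.06 without both BCSP libraries of round 2.

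The other 21 lists were not called over both cell types, with camera adjusted p of 0.0839 to 0.96. Among skeletal lists, medians were -0.26 for hypertrophic chondrocyte, -0.03 for osteoblast, 0.03 for adipogenic and marrow stromal, and 0.16 for stem cell and sort marker genes. Among signalling lists they were -0.009 for BMP, 0.07 for Wnt, 0.11 for Hedgehog, 0.21 for Notch, 0.06 for interferon and 0.10 for senescence and p53 genes. DNA methylation machinery genes had a median of 0.03, imprinted genes 0.006, germline genes under promoter methylation 0.18, and immediate-early and heat-shock genes -0.02. Markers of other cells had medians of -0.66 (erythroid), -0.52 (neutrophil), -0.01 (macrophage and osteoclast), -0.82 (lymphoid), -0.05 (skeletal muscle), -0.07 (Schwann cell) and 0.41 (keratinocyte). With members at 0 in a whole group set at 3 counts, the neutrophil median was -0.31.

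No gene passed for the interaction, the difference of the genotype effect between SSC and BCSP, by edgeR, DESeq2 or limma-voom. The edgeR test had 282 genes at an unadjusted p under 0.05, DESeq2 414 and limma-voom 194. The genes of lowest p among those with at least 5 CPM were Hilpda, a lipid droplet gene induced by hypoxia (0.99 ± 0.39), Gpr37l1, an orphan receptor gene (1.03 ± 0.43), the centromere gene Cenpi (1.29 ± 0.54), the mitochondrial ribosome gene Mrps2 (0.83 ± 0.36) and the DNA damage checkpoint gene Rad1 (0.87 ± 0.39). On the lower side they were Mcoln3 (-1.56 ± 0.61), the scaffold gene Mapkbp1 (-0.80 ± 0.35), the recombinase gene Dmc1 (-1.04 ± 0.47), Bahcc1 (-0.73 ± 0.33) and the microtubule protein gene Map1a (-0.65 ± 0.30), all with an edgeR adjusted p of 1. The effect on Trf differed by 0.55 ± 0.39 between the populations (edgeR adjusted p = 1). Oxidative phosphorylation genes had a median interaction of 0.38 with 27 of 28 above 0 (camera adjusted p = 0.000118, adjusted p = 0.918 with an estimated correlation). That is, their fold change of KO over wild type was lower in BCSP than in SSC. Ndufs7 was at 0.71 ± 0.39. Blood cell lists had medians of -3.00 (erythroid), -5.35 (neutrophil) and -1.31 (mast cell and megakaryocyte) at low counts. Their camera adjusted p were 6.72e-05, 0.0035 and 0.0153, with adjusted p = 0.733, 0.918 and 0.733 with an estimated correlation. Interaction values correlated with exon length at Spearman -0.473.

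The 4 interaction calls on lists each depended on single libraries. The oxidative phosphorylation call was lost without wild-type BCSP library 2 (-0.01, camera adjusted p = 0.714), KO BCSP library 2 (0.10, 0.621), wild-type SSC library 2 (0.15, 0.491) and KO SSC library 1 (0.13, 0.108). The erythroid call was lost without wild-type SSC library 1 (-0.44, camera adjusted p = 0.252). Neutrophil genes turned to 2.31 without that library (camera adjusted p = 0.00187). Their call was lost without KO BCSP library 1 (-0.81, 0.544), wild-type BCSP library 2 (-4.34, 0.331) and KO SSC library 2 (-4.51, 0.135). The mast cell call was lost without wild-type SSC library 1 (0.0603), KO SSC library 2 (0.0697), wild-type BCSP library 1 (0.205) and KO BCSP library 1 (0.235). Medians also moved for oxidative phosphorylation, to 0.65, 0.67 and 0.68 without wild-type SSC library 1, wild-type BCSP library 1 and KO BCSP library 1. They were -1.86 for erythroid genes without KO BCSP library 1, -9.86 for neutrophil genes without wild-type BCSP library 1, and -3.24 and -2.97 for mast cell genes without KO SSC library 1 and wild-type BCSP library 1. The fry test called 1 list, mast cell and megakaryocyte.

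Between the 2 populations, the one gene that passed was Eng, which encodes endoglin (CD105), the surface protein that separates SSC from BCSP in sorting. Eng (chr2:32646595-32682669) stood at 3.30 ± 0.838 CPM in SSC and 49.2 ± 1.8 CPM in BCSP of wild type (SD, n = 2), a log2 fold change of -3.90 ± 0.31 (edgeR adjusted p = 0.000337). In KO it stood at 2.54 ± 0.0154 and 34.8 ± 12.9 CPM (-3.78 ± 0.31, edgeR adjusted p = 0.000477). As a gate gene it checks the sort and is no finding. The other sort genes did not pass in wild type: Itgav was at -0.18 ± 0.27, Cd200 at -0.50 ± 0.47, Enpep at -0.46 ± 0.45 and Thy1 at -0.95 ± 0.73. Thy1 (0.354 and 0.681 CPM), Tek (0.0230 and 0.00874) and the leukocyte gene Ptprc (0.554 and 0.00437) were counted at low levels in wild-type SSC and BCSP.

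Genes next in order between wild-type SSC and BCSP did not pass (edgeR adjusted p = 1). Cytl1, a cytokine-like gene of cartilage, stood at 44.0 ± 5.41 CPM in SSC and 132.5 ± 75 in BCSP (-1.59 ± 0.33). The Wnt inhibitor gene Wif1 stood at 138 ± 1.52 and 319 ± 35.7 CPM (-1.21 ± 0.28), the integrin-like gene Itgbl1 was at -1.13 ± 0.26 and Serpinf1, an inhibitor of vessel growth, at -1.03 ± 0.24. Higher in SSC were the actin-bundling gene Lcp1 (0.85 ± 0.22), the nitric oxide synthase gene Nos1 (1.16 ± 0.33) and the sulfatase gene Arsi (0.88 ± 0.25). Runx3, a transcription factor gene of chondrocyte maturation, was at 0.85 ± 0.27 and the chromatin remodeller gene Chd7 at 0.89 ± 0.28. The edgeR test called 1 gene, with 550 at an unadjusted p under 0.05, while DESeq2 called 2, Eng and Cytl1. Cytl1 was also called by edgeR without wild-type BCSP library 1 (-2.07).

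Tendon, ligament and fibrous matrix genes were the list with the lowest p between wild-type SSC and BCSP. Their median was -0.40 with 19 of 22 below 0 (camera adjusted p = 7.07e-08, adjusted p = 0.522 with an estimated correlation). Tnmd was at -0.95 ± 0.27 and the collagen gene Col14a1 at -0.73 ± 0.23. Hypertrophic chondrocyte genes, with Runx3, had a median of 0.29 and 12 of 14 above 0 (camera adjusted p = 0.015, adjusted p = 0.754 with an estimated correlation). Stem cell and sort marker genes, with Eng, had a median of -0.22 (camera adjusted p = 0.000874, adjusted p = 0.55 with an estimated correlation). S-phase genes, with Mcm3 (-0.40 ± 0.25), had a median of -0.25 (camera adjusted p = 0.00374, adjusted p = 0.897 with an estimated correlation). Oxidative phosphorylation genes, with Cox4i1 (-0.61 ± 0.33), had one of -0.25 (camera adjusted p = 0.00266, adjusted p = 0.897 with an estimated correlation). Erythroid genes had a median of 1.06 (camera adjusted p = 0.0394, adjusted p = 0.754 with an estimated correlation) and mast cell genes 0.67, or 0.38 with 2 genes at 0 in a group set at 3 counts (camera adjusted p = 0.0358, adjusted p = 0.55 with an estimated correlation). Apart from Eng, no member of these lists passed by edgeR over all genes, and fold changes correlated with exon length at Spearman 0.403.

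The tendon call in wild type held without each library, at -0.20 without wild-type BCSP library 2. Without wild-type SSC library 1 the calls on hypertrophic (0.676), sort marker (0.0607), erythroid (0.48, median -0.19) and mast cell genes (0.0607) were lost. Without wild-type SSC library 2, S phase (0.825, median -0.06), oxidative phosphorylation (0.867, median -0.01) and mast cell (0.0876) were lost. Leaving out wild-type BCSP library 1, sort marker (0.0603) and mast cell (0.258) were lost, and hypertrophic genes moved to 0.87. Without wild-type BCSP library 2, hypertrophic (0.606, median 0.12), oxidative phosphorylation (0.455, median 0.05) and erythroid (0.455) were lost, and erythroid also without KO BCSP library 1 (0.052). All values in parentheses are camera adjusted p unless called medians. Medians also moved to -0.09 (sort markers), -0.47 (S phase) and -0.47 (oxidative phosphorylation) without wild-type SSC library 1, to 0.54 (hypertrophic) and 1.995 (erythroid) without wild-type SSC library 2, to 0.01 (sort markers), -0.50 (oxidative phosphorylation), 1.68 (erythroid) and 1.37 (mast cell) without wild-type BCSP library 1, and to -0.13 (sort markers) and 1.09 (mast cell) without wild-type BCSP library 2.

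In KO, the genes after Eng did not pass between SSC and BCSP either (edgeR adjusted p = 1). Higher in SSC were Arsi (40.1 ± 10.6 and 17.4 ± 0.575 CPM, 1.20 ± 0.25), Runx3 (1.16 ± 0.27), the growth factor gene Bmp7 (44.4 ± 2.73 and 22.2 ± 0.823 CPM), the Wnt ligand gene Wnt5b (0.95 ± 0.25) and the collagen gene Col26a1 (1.25 ± 0.33). Lower were Cxcl12 (6.54 ± 1.42 and 14.7 ± 1.37 CPM, -1.17 ± 0.28), the matrix gene Olfml2b (-0.93 ± 0.27), Serpinf1 (-0.82 ± 0.24) and Itgbl1 (-0.85 ± 0.26). Among sort genes, Itgav was at -0.34 ± 0.27, Cd200 at -0.35 ± 0.47, Enpep at -1.39 ± 0.46 and Thy1 at 0.76 ± 0.72, with Tek (0.2 and 0.0899) and Ptprc (0.0489 and 0.201) at low CPM. The edgeR test called 1 gene, with 338 at an unadjusted p under 0.05, and DESeq2 called 2, Eng and Igkc. Eng passed without each library in both genotypes, at -4.18 to -3.66 in wild type and -4.11 to -3.34 in KO.

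The tendon, ligament and fibrous matrix list again had the lowest p in KO. Its median was -0.29 with 18 of 22 below 0 (camera adjusted p = 2.52e-06, adjusted p = 0.336 with an estimated correlation). Col14a1 was at -0.59 ± 0.23 and Thbs2 at -0.56 ± 0.24. Hypertrophic genes had a median of 0.18 (camera adjusted p = 0.0244, adjusted p = 0.764 with an estimated correlation), and Col10a1, the collagen gene of hypertrophic cartilage, stood at 532 ± 491 and 203 ± 14.1 CPM. Adipogenic and marrow stromal genes, with Cxcl12, had a median of -0.25 and 14 of 20 below 0 (camera adjusted p = 0.00658, adjusted p = 0.336 with an estimated correlation). Sort marker genes, with Eng, had a median of -0.06 (camera adjusted p = 0.00386, adjusted p = 0.336 with an estimated correlation). Senescence genes, with the binding protein gene Igfbp5 (-0.90 ± 0.31), had a median of -0.13 (camera adjusted p = 0.0224, adjusted p = 0.336 with an estimated correlation). TGF-beta genes, with Ltbp2 (-0.98 ± 0.32) and Tgfbi (0.87 ± 0.31), had one of -0.10 (camera adjusted p = 0.0213, adjusted p = 0.336 with an estimated correlation). Erythroid genes had a median of -1.22 (camera adjusted p = 0.00011, adjusted p = 0.336 with an estimated correlation) and neutrophil genes -1.95 (camera adjusted p = 0.0226, adjusted p = 0.896 with an estimated correlation), both at low counts. Apart from Eng, no member passed by edgeR over all genes, and fold changes correlated with exon length at Spearman -0.148.

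The tendon call in KO held without each library, at -0.45 without KO SSC library 2. Without KO SSC library 1 the calls on hypertrophic (0.452, median -0.13), adipogenic (0.22), sort marker (0.23), senescence (0.217) and TGF-beta genes (0.23) were lost. Without KO BCSP library 1, adipogenic (0.204), senescence (0.253), TGF-beta (0.118), erythroid (0.0945) and neutrophil genes (0.187, median 2.13) were lost. Without KO BCSP library 2, hypertrophic (0.832) and TGF-beta (0.0693) were lost and the sort marker median was 0.15, and without KO SSC library 2 the neutrophil call was lost (0.476), while hypertrophic genes moved to 0.66. These values are camera adjusted p unless called medians. Medians also moved without KO SSC library 1 to -0.11 (adipogenic), 0.05 (sort markers), -0.06 (TGF-beta), -1.90 (erythroid) and -3.70 (neutrophil), and without KO SSC library 2 to -0.46 (adipogenic), -0.19 (sort markers), -0.23 (senescence), -0.17 (TGF-beta) and -1.23 (neutrophil). Without KO BCSP library 1 they were 0.74 (hypertrophic), -0.14 (adipogenic), -0.08 (senescence) and -0.67 (erythroid), and without KO BCSP library 2 they were 0.05 (hypertrophic), -0.16 (adipogenic), -0.05 (TGF-beta) and -1.97 (erythroid).

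Genotype effects in SSC and BCSP correlated at Pearson 0.129 across 22153 genes, with 64.7% of the genes on the same side of 0. Among the 9523 genes with a mean of at least 5 CPM, the correlation was 0.502 with 73.6% on the same side. Genes are not independent of one another, so no p-value is given for either. Both effects followed exon length in the same direction over those 9523 genes (Spearman 0.283 in SSC and 0.513 in BCSP). Y-linked genes also lay higher in KO in both populations. Whether such shared shifts or shared animals made the agreement was not tested, so it is no measure of an effect of Tet1 alone. Of the 427 tested genes within 20 Mb of Tet1, 0 passed over both cell types by edgeR, against 3 of 21692 elsewhere (Fisher exact p = 1). At an unadjusted p under 0.05 there were 57 near Tet1 (13.4%) against 7.81% elsewhere (Fisher exact p = 9.07e-05). Genes are the units of that test too, so its p-value may be too small. In SSC alone the shares were 1.17% near and 1.2% elsewhere, and in BCSP 8.67% and 6.14%. Over both cell types, genes of lowest p near Tet1 included Zfp365 (chr10:67886103-67912662, 1.26 ± 0.23) and the zinc-finger gene Zfr2 (0.68 ± 0.16). Another was the long noncoding gene A930033H14Rik (0.92 ± 0.23). DESeq2 called Zfp365 over both cell types (adjusted p = 0.000304).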

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

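The tests of Trf against Xist and of single BCSP libraries were chosen only after the results they bear on were seen. What stood out here is a difference between groups: in 4 gene lists the genotype effect in SSC differed from that in BCSP by camera. Oxidative phosphorylation genes had a median interaction of 0.38, erythroid genes -3.00, neutrophil genes -5.35 and mast cell and megakaryocyte genes -1.31. With an estimated correlation none of the 4 passed, at camera adjusted p of 0.918, 0.733, 0.918 and 0.733, and no single gene passed by edgeR (282 at an unadjusted p under 0.05), while DESeq2 also called 0. The blood cell lists rest on low counts, and with members at 0 in a whole group set at 3 counts the neutrophil median was -4.74. Neutrophil genes lay above their mean in every library of round 1 and below it in every library of round 2, at 3.41 in wild-type SSC library 1 and 2.70 in KO BCSP library 1. Leaving out wild-type SSC library 1 turned the neutrophil median to 2.31 and took the erythroid one to -0.44.

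Trf fell in both populations, and the 3 genes called over both cell types were set against other splits of the libraries. Counting the real one, 2 of 34 splits of the 8 libraries into 4 and 4 called at least as many genes, with 3 in the real split and 222 in the highest other. That is not under the 5% of splits set to argue against chance, so chance stays open for the count of 3. At an unadjusted edgeR p under 0.05, another split had 3867 genes against 1753 in the real one. The split of SSC against BCSP could not be fitted beside cell type and is not counted. The split with 222 calls is round 1 against round 2, which points to a structure of the samples. With the round as a block edgeR called 28 genes over both cell types. Liver RNA in the wild-type libraries is argued against by the hepatocyte genes, which summed to 0.551 CPM where Trf averaged 25.2 CPM. A larger male share among the KO pups alone is argued against by Xist, since Trf lay below it by -1.84 (SE 0.453). A strain haplotype at Trf stays open: 6.8% of genes within 5 Mb had an unadjusted p under 0.05 against 7.92% elsewhere (Fisher exact p = 0.759), which a change in 1 gene alone would not alter. A direct or indirect effect of losing Tet1 on Trf was not tested and stays open too.

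Oxidative phosphorylation genes lay lower in KO BCSP (median -0.51), where fold changes followed exon length. Among random lists matched on length and expression, the median sat at percentile 0.48 (matched median -0.362, central range -0.477 to -0.222). That is below the central range, the result set to argue against length as the whole cause. Genes of those lists were drawn independently, while genes of 1 pathway can move together, so the range may be too narrow. A shift with length therefore stays open in BCSP, and in SSC too, where the list sat at percentile 27.1. KO BCSP library 2 as the sole source is argued against by a median of -0.267 without it, with the camera call kept. For wild-type BCSP library 2 the source cannot be told apart from a genotype effect, because without it the median was -0.178 and the call was kept. Leaving out 1 library does not test the 2 BCSP libraries of round 2 together. Without both the median was 0.098, so the fall rests on those 2 libraries. The list's median deviation from each gene's mean log2 CPM was -0.004 in wild-type and 0.047 in KO BCSP library 1. In library 2 it was 0.605 and -0.531. A genotype effect on respiration genes seen only in round 2 cannot be told apart from a trait of those 2 libraries.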

How the results depend on the processing

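Outside the Y-linked covariate, most results kept their direction, and the count of called genes moved with the test, the filter, the block and the covariate; the cause was not tested unless named. The tallies that follow leave out the Y-linked covariate except for Trf and Tet1. Of 3097 values of named genes under alternatives, 2950 kept their direction and side of the threshold, 75 passed where the main test did not, 30 no longer passed and 42 reversed. Most named genes did not pass in the main test, so a kept value mostly means that they still did not. The 30 fall on the few that passed. Of 735 values of called lists, 499 were kept, 218 no longer passed and 18 reversed. In the order SSC, BCSP, both, interaction, wild-type SSC against BCSP and KO SSC against BCSP, the edgeR counts were 1, 1, 3, 0, 1 and 1. Without a filter they were 4, 38, 234, 0, 5 and 2, and Tet1 passed over both cell types (-0.70, edgeR adjusted p = 0.0483). DESeq2 gave 9, 20, 103, 0, 2 and 2. Correlations between groups over the rounds were 0.0234 to 0.240, over 0.1 in 4 of 6 pairs of groups where all 6 were needed to treat the numbers as pairs, though 222 genes differed between the rounds and the labels do not say what a round is. With the round as a block edgeR gave 2, 3, 28 (10 higher and 18 lower), 2, 3 and 2, and the block took the interaction lists from 4 to 9. The strict filter and the mean of the 2 contrasts gave 1 gene each over both cell types. RLE scaling, a fold minimum and fitting only the 4 libraries compared left the gene counts as they were. Added after the data were seen were limma-voom, the Y-linked covariate and the fit without both BCSP libraries of round 2. Limma-voom gave 8 over both cell types and the main counts elsewhere. With the Y-linked covariate edgeR called 0 genes in SSC, BCSP and both, with Trf at -2.01, -2.48 and -2.18, Tet1 at -1.83, -1.46 and -1.64 where the main test gave -0.89, -0.52 and -0.70, and 2, 3 and 3 lists. That level differs with genotype, so the model has less to tell the 2 apart by. Under it 14 of 42, 12 of 41 and 16 of 45 named genes and 8 of 13, 7 of 13 and 8 of 14 lists changed side, with 1 list in each comparison called on the other side and 0 kept. Single values under that covariate are given only for Trf and Tet1, a choice made after they were seen. Without both BCSP libraries of round 2, a fit with fewer samples, edgeR called 0 genes in BCSP and 1 over both, and camera 8 lists in BCSP. In that fit Tet2 (-0.081), Dnmt1 (-0.14), Dnmt3a (-0.0067) and Scrg1 (0.0046) reversed in BCSP, and Dnmt1 (-0.081) and Dnmt3a (-0.047) over both. So did camera for cartilage (0.070), glycolysis (-0.0018), oxidative phosphorylation (0.098) and ER stress genes (-0.082, the direction of the test and not of the median). Dnmt1 over both was -0.032 by limma-voom. With an estimated correlation camera called 0 lists in each of the 6 comparisons (lowest adjusted p 0.553, 0.423, 0.384, 0.733, 0.522 and 0.336), and fry called 0, 2, 0, 1, 1 and 0. The agreement of the genotype effects was 0.502 in genes of at least 5 CPM against 0.129 in all. Near Tet1 the Fisher exact p on called genes was 1 within 10 Mb and 0.137 over the chromosome, while the share at an unadjusted p under 0.05 was 14.8% (p = 0.00468) and 11.3% (p = 6.83e-05). Leaving out 1 library at a time, gene counts ran from 0 to 1 in SSC, 1 to 3 over both and 1 to 2 in wild type, with BCSP at 1, KO at 1 and the interaction at 0. Lists ran from 5 to 18 in SSC, 8 to 13 in BCSP, 7 to 18 over both, 3 to 7 for the interaction, 6 to 9 in wild type and 5 to 15 in KO. Tet1 ran from -0.90 to -0.53 over both. Results that reversed without 1 library are given from lowest to highest. In SSC these were Tet2 (-0.042 to 0.58), Tet3 (-0.038 to 0.28), Dnmt3a (-0.30 to 0.21), Col2a1 (-0.16 to 0.012), Sparc (-0.059 to 0.15), Prg4 (-0.28 to 1.13), Ube2c (-1.32 to 0.12), Cox6c (-0.69 to 0.22) and Nkg7 (-7.28 to 0). SSC lists were inflammatory (-0.23 to 0.78), S phase (-0.54 to -0.036, where camera turned and the median did not), G2 and M phase (-0.91 to 0.29) and oxidative phosphorylation (-0.37 to 0.097). Medians that crossed 0 while the direction of camera stayed were tendon in SSC (-0.040 without KO SSC library 2), cartilage in BCSP (0.011 without wild-type BCSP library 2), endothelial in BCSP (-0.0997 without both of round 2) and oxidative phosphorylation for the interaction (-0.011 without wild-type BCSP library 2). The others were sort markers in wild type (0.012 without wild-type BCSP library 1) and in KO (0.051 without KO SSC library 1 and 0.15 without KO BCSP library 2). In BCSP the results that reversed were Tet1 (-0.92 to 0.054), Dnmt1 (-0.13 to 0.32), Ppbp (0 to 8.66) and the glycolysis list (-0.79 to 0.055). Over both they were Dnmt1 (-0.082 to 0.093) and Dnmt3a (-0.030 to 0.18). For the interaction they were Tet1 (-0.95 to 0.035), Dnmt1 (-0.38 to 0.078), Dnmt3a (-0.46 to 0.043), Ppbp (-9.42 to 0.015) and the neutrophil list (-9.86 to 2.31). In wild type they were Itgav (-0.55 to 0.32), Enpep (-0.85 to 0.072), Tek (-0.11 to 4.62), Tet1 (-0.29 to 0.68), Cox4i1 (-1.06 to 0.043), Uqcrfs1 (-0.73 to 0.013), and the oxidative phosphorylation (-0.50 to 0.047) and erythroid lists (-0.19 to 1.995). In KO they were Cd200 (-0.83 to 0.38), Tek (-3.19 to 3.02), Tet1 (-0.66 to 0.043), Col10a1 (-0.14 to 2.10), Cebpe (-7.42 to 0), Ly6g (-7.20 to 0), and the hypertrophic (-0.13 to 0.74) and neutrophil lists (-3.70 to 2.13). Nkg7, Ppbp, Cebpe, Ly6g and Tek have groups at or near 0 counts, so their fitted values are no bounds. Depth limits little here, at more than 100 counts per CPM, and the spread between 2 libraries sets the precision. In SSC, 26.9% of simulated 2-fold changes were recovered, a share that may be too high for the real data, where fewer genes passed.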

Other observations

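Tests of Y-linked spread, of the foot plate, of windows along the genome, of gene pairs and of length near Tet1 were chosen only after the results they bear on were seen. The libraries of round 1 and round 2 differed in some limb patterning genes, a comparison made after the data were seen. These genes were picked after the calls and not tested as a list. Over 4 libraries against 4, balanced over genotype, edgeR called 222 genes, 93 higher and 129 lower in round 1. Hoxd13 and Hoxa13, which pattern the foot and hand plate, averaged 24.8 ± 4.11 and 8.38 ± 3.43 CPM (SD, n = 4) in round 1 and 0.181 ± 0.153 and 1.7 CPM in round 2 (edgeR adjusted p = 0.000435 and 0.00712). Sall1 (5.34 against 0.274 CPM, edgeR adjusted p = 0.000435), Evx2 (3.78 against 0.293), Irx1 (4.53 against 0.593) and Lhx2 (1.97 against 0.429) rose with them. Lower in round 1 were Meis1, a mark of the upper limb segments (3.68 ± 0.374 against 8.35 ± 0.528 CPM, edgeR adjusted p = 0.0137), Meis2 (2.3 against 5.61), Tbx3 (4 against 9.91) and Hoxc10 (18.7 against 32.5). Hoxa10 (30.9 against 33 CPM, edgeR adjusted p = 0.909), Hoxa9 (0.832) and the hindlimb gene Tbx4 (0.993) did not differ past the threshold. Nor did, among others, Hoxa11 (edgeR adjusted p = 0.0994), Hoxd10 (0.103), Shox2 (0.131), Pitx1 (0.287) and Hoxd9 (0.627).

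Bone-forming genes also differed between the rounds. Of 24 osteoblast genes, 8 were higher in round 1 and 0 lower by edgeR, with a median log2 difference of 0.78. Ibsp averaged 42 against 12.5 CPM (edgeR adjusted p = 0.0172), Spp1 130 against 71 (0.0208), Omd 335 against 119 (0.0208) and Alpl 83.9 against 43 (0.032). The metallothionein gene Mt1 was lower, at 197 against 484 CPM (edgeR adjusted p = 0.00683), as were the transcription factor genes Cebpb (194 against 395, 0.0348) and Nfatc2 (456 against 913, 0.0436). Neutrophil genes were higher in 4 of 17 cases, and macrophage and osteoclast genes in 2 of 17. Median log2 differences, round 1 over round 2, were 0.64 for G2 and M phase genes and -0.75 for inflammatory genes. In SSC their genotype medians were smaller.

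Whether the libraries of round 1 held cartilage of the foot plate beside the femur stays open. Hoxa13 and Hoxd13 summed to at least 22.4 CPM in each library of round 1 and at most 2.59 CPM in round 2, but these genes gave rise to the idea and so do not test it. Tbx5 was lower in round 1 than in round 2 (-0.79 ± 0.17). This argues against a larger share of forelimb tissue in round 1, the hand plate included. Its level was 16.1 to 42% of that of Tbx4 in round 1. That is not under the 5% set to argue against any forelimb tissue, which stays open. Tail or trunk cartilage stays open. Hoxb13, Hoxc12 and Hoxc13 summed to at most 3.32 CPM in round 1 and at least 4.88 CPM in round 2. They passed 1 CPM in each library of round 1, as predicted for it, but that bound was ill chosen since round 2 lay higher, and the share under 5% of Hoxa13 and Hoxd13 that was to argue against it was not reached.

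Genes near Tet1 may carry sequence of the 129 strain from the targeted cells, a hypothesis tested on the same data. Within 20 Mb, 13.4% of 427 genes had an unadjusted p under 0.05 against 7.81% elsewhere (Fisher exact p = 9.07e-05, with genes as units). That share was above 99.8% of 511 windows along the genome, and of 495 windows clear of Tet1, 1 had a share at least as high. Neighbouring windows overlap and share many genes, so far fewer separate windows stand behind these counts. Random sets matched on length and expression stayed below the share near Tet1 (percentile 100), the result set to argue against length as the cause. Their genes were drawn independently, while neighbouring genes can move together, so their range may be too narrow and length stays open. In SSC alone the shares were 1.17% near and 1.2% elsewhere, and in BCSP 8.67% and 6.14%. Flanking sequence would be present in both populations, so 129 sequence as the explanation stays open. The whole chromosome held 11.3% and windows at its far end 11.9 to 12.9%, so the excess is not confined to the flank of Tet1. Strain haplotypes elsewhere stay open: the 100 genes of lowest p held 32 pairs within 2 Mb (random median 13), but 18 on autosomes without H2 genes (random median 14, upper bound 23). Nnt, partly deleted in C57BL/6J, was at 0.13 ± 0.94 with 0.292 and 0.305 CPM in the 2 genotypes, too few counts to decide. For Nnt, these haplotypes and the clock below, the bar for a decision was raised after the values were seen.

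The Y-linked genes and Xist may reflect a larger male share among the KO pups, which the labels leave open. The 4 Y-linked genes moved by near the same factor, with a spread of 0.39 in log2 fold change, and Xist was at -1.14 ± 0.40 over both cell types. The pattern did not hold in each pair of libraries. In BCSP library 2, Xist stood at 276.8 CPM in wild type and 275.2 in KO, while Ddx3y stood at 23.2 and 92.2. Another time of day at collection was tested with clock genes. Those that peak with Dbp and Per3 had a median of 0.322 and those that peak with Arntl 0.194, the same direction where a shift in time would part them. The second value lay within its spread, so the timing stays open, with Per3 at 0.95 ± 0.21.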
